A study of Mus musculus with 12 samples.

How the data were processed

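Gene expression was measured by poly-A RNA sequencing in 12 mouse samples, as 4 groups of 3: livers with ABHD6 overexpression or GFP after 8 weeks of a diet with 60% of its calories from fat, and primary hepatocytes with an ABHD6 siRNA or a scrambled siRNA. The authors deposited a table of raw counts per gene, with 1 column per library and no normalization, and the submitters' processing notes name HISAT2, DESeq2 and genome build mm39 without tool versions. The deposited FPKM values were made by the authors from these counts. Each equals the count divided by the gene length in the table and by 1 scaling number per library, with a largest relative deviation between genes of 4.97e-10. That number was 0.671 to 0.780 times the library total in livers and 1.25 to 1.27 times in hepatocytes, so FPKM carries a normalization beyond library size. The program that counted reads, the annotation release, the strandedness and the read layout were not given in the sources used here. Each measurement column matched 1 sample, with 0 columns left over, and 0 of the 56748 genes lacked a name.

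Library totals ran from 13303141 to 15119953 in overexpressing livers, from 15052684 to 16234658 in GFP livers, from 12295733 to 14453320 in siABHD6 hepatocytes and from 12395020 to 13687998 in siScramble hepatocytes. Between 19776 and 20934 genes had a count in a library. The spread between replicates exceeded counting noise in every pair, with a biological coefficient of variation in edgeR of 28.1% in livers and 4.93% in hepatocytes.

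Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, a quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, with calls at an adjusted p under 0.05 and no fold threshold. The difference between the responses was fitted on all 12 libraries as a contrast of contrasts. CPM values of single genes are counts scaled to the TMM effective library size of the comparison's 6 libraries, and log2 CPM uses a prior count of 2. Sums over cell type markers use the library total instead. Overlap between comparisons was set against independent lists with one-sided Fisher's exact tests, and fold changes were correlated across genes without a p-value.

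Gene lists were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over all lists with at least 5 tested genes. There were 44 lists, fixed before the data were examined, for pathways, cell type markers and sample quality. Camera was repeated with the correlation estimated per list, and fry was run as another test. Within a list, genes were counted as called over all genes tested, and again adjusted over the list alone. The mean log2 CPM of a list per library was compared by an exact permutation test, for which 0.1 is the smallest two-sided p.

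Genes named in the text followed a rule set before the data were examined: Abhd6, the 6 largest increases and 6 largest decreases among protein-coding genes called with a mean log2 CPM of at least 1 and groups that did not overlap, genes of the study's subject, and the leading genes of called lists. In livers, where no gene was called, the rule gave the 3 genes with the smallest p in each direction. Other genes are stated to be named after their values were seen. Values of some genes that the rule gives are not reported here.

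Alternatives set before the data were examined were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in every library, DESeq2 1.42.0, limma-voom, FPKM with pseudocounts of 1 and 0.1, protein-coding genes only, a fold threshold of 1.5, a single fit over all libraries, the replicate number as a block, other list tests, and leaving out each library in turn. For a gene that was not called, keeping its result means staying uncalled. Leaving out livers GFP 3 and ABHD6 OE 1, and a covariate for the acute phase list, were added after the data were seen. Replicate numbers were checked for pairing by correlating deviations from the group means between equal numbers, which gave -0.42, 0.44 and -0.13 in livers and -0.0107 to -0.00354 in hepatocytes, so no pairing was assumed.

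For siRNA pairing, each 7-base word was scanned in 3' UTRs of at least 50 bases from GENCODE annotation of an earlier genome build, joined by gene identifier, so no coordinates were mixed. A UTR was found for 11619 of 11780 tested protein-coding genes in hepatocytes (98.6%). Words present in at least 50 genes were tested by regression of the gene's signed z value on presence of the word, with UTR length and GC content as covariates and a two-sided Bonferroni limit. This part and the figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

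The edgeR steps were tested on simulated counts with planted changes. In the liver setting 0%, 18.2% and 80% of genes changed 1.5-, 2- and 4-fold were called, and 13.5% of calls were unchanged genes. In the hepatocyte setting these were 75.8%, 89.2%, 100% and 7.96%. Genes were simulated independently of each other, so variation shared between genes is missing. The shares need not hold in the real data, least of all in livers. The word scan found a planted word, and 0 words passed its limit in permuted data.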

Results

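Poly-A RNA was sequenced from 12 mouse samples in 4 groups of 3. Of these, 6 were livers of mice fed a diet with 60% of its calories from fat for 8 weeks. In 3 of these livers ABHD6 was overexpressed, by an adeno-associated virus with a hepatocyte-directed promoter according to the series text, and the other 3 were GFP controls. The other 6 samples were primary hepatocytes, which are liver parenchymal cells taken into culture. In 3 of them an siRNA against ABHD6 was used (siABHD6) and in 3 a scrambled siRNA (siScramble). ABHD6 is a serine hydrolase that cleaves monoacylglycerols, and the title of the series places it beside the kinase Akt and the transcription factor FoxO1 in metabolic health. Each library held between 12295733 and 16234658 counts over the 56748 genes of the table. The labels call the samples biological replicates but do not state whether the hepatocyte replicates were separate cultures, so p-values there measure the spread between these samples, which may be technical. Counts of replicates differed by more than sampling noise in every pair, with a chi-square per gene of 2.59 to 4.01 in hepatocytes and 17.5 to 240 in livers.

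The targeted gene moved with the labels in both systems. Abhd6 (ENSMUSG00000025277; mm39 chromosome 14, 14413010 to 14466871, minus strand) was at 5.09 ± 0.164 CPM (SD, n = 3) in siABHD6 hepatocytes. It was at 34.8 ± 1.80 CPM (SD, n = 3) in siScramble hepatocytes. It fell by 2.77 (SE 0.10) on the log2 scale, to 0.147 times the control level, with an adjusted p of 3.14e-13 in edgeR's quasi-likelihood test. In livers it was at 147 ± 40.2 CPM (SD, n = 3) with overexpression and at 35.7 ± 10.1 CPM (SD, n = 3) with GFP. Its log2 fold change there was 2.04 (SE 0.28), and each overexpressing liver lay above each GFP liver. That difference did not pass edgeR's threshold (unadjusted p = 0.00015, adjusted p = 1.00) and did in DESeq2 (adjusted p = 3.44e-09), in a single edgeR fit over all 12 libraries (adjusted p = 0.0113) and in edgeR without the filter on low counts (adjusted p = 0.0237). Over the other settings tried for it, which include leaving out each library, the adjusted p ranged from 0.200 to 1.00.

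**Figure D1:**
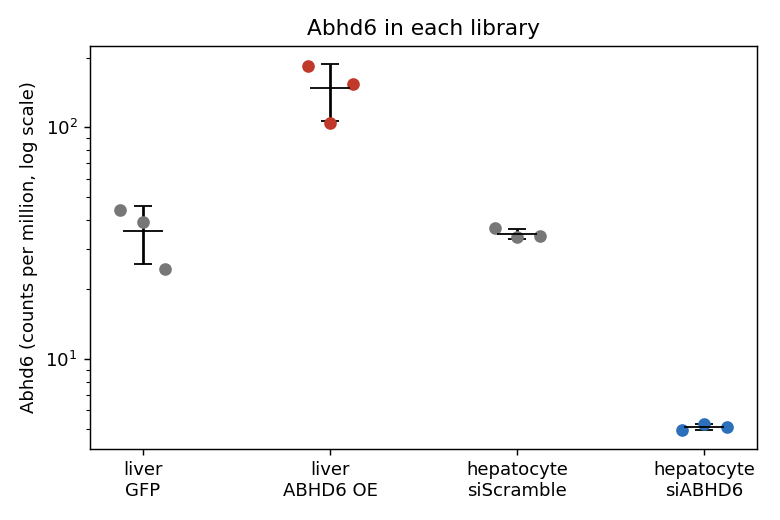
Abhd6 in CPM (log axis) in each of the 12 libraries, by group. Points are libraries, and bars give the mean and SD of 3 libraries; the group means are 35.7, 147, 34.8 and 5.09 from left to right.

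The first comparison asked what changed in hepatocytes when Abhd6 was knocked down. Of the genes that passed, those on the cell cycle list rose, and most of those on the lists of the unfolded protein response (protein folding in the endoplasmic reticulum), the amino acid response and the interferon response fell. None of these lists kept its call with an estimated correlation between genes. Of 13449 genes tested, 2075 passed edgeR's threshold (adjusted p under 0.05), of which 1051 were higher and 1024 lower with siABHD6. Most changes were small, with a median absolute log2 fold change of 0.27 among the genes called, and 96 genes changed at least 2-fold (46 higher and 50 lower). The groups did not overlap for 31.2% of the genes tested, where chance gives 10%.

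The largest increases among protein-coding genes that met the naming rule were of Npr3, the clearance receptor for natriuretic peptides (log2 fold change 1.62, SE 0.22), the sodium channel gene Scn7a (1.56, SE 0.28), the transporter gene Abcc12 (1.51, SE 0.27), the serpin gene Serpinb9b (1.46, SE 0.14), the transcriptional corepressor gene Ctbp2 (1.38, SE 0.23) and the myosin gene Myo7b (1.36, SE 0.26). These 6 had adjusted p-values in edgeR of 0.000989 or lower. The largest decreases were of the lysine methyltransferase gene Eef1akmt4 (-3.32, SE 0.24), the urinary protein gene Mup15 (-3.21, SE 0.52), Iscu, which encodes the scaffold on which iron-sulfur clusters are built (-2.24, SE 0.08), Dio3, which encodes a deiodinase that inactivates thyroid hormone (-2.14, SE 0.19), the proprotein convertase gene Pcsk6 (-1.62, SE 0.05) and Hrk, which encodes a pro-apoptotic BCL2-family protein (-1.53, SE 0.30). Their adjusted p-values in edgeR were 0.00108 or lower. Iscu went from 53.1 ± 3.45 to 11.2 ± 1.01 CPM (SD, n = 3 each) and Serpinb9b from 5.88 ± 0.900 to 16.2 ± 1.43 CPM (SD, n = 3 each). Mup15 belongs to a family of near-identical genes and was at 425 ± 357 CPM (SD, n = 3) in siScramble hepatocytes, so its value is uncertain. Eef1akmt4 overlaps Alg3 on the opposite strand, Pcsk6 overlaps the noncoding gene Gm20684 on the opposite strand and the record of Ctbp2 overlaps Fgfr2. The strand used in counting was not given in the sources used here.

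In the cell cycle list, 26 of 39 genes rose and none fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 0.45. Ccnd1, which encodes the G1 cyclin D1, rose by 1.14 (SE 0.11), the mitotic regulator gene Cdc20 by 0.94 (SE 0.11) and the proliferation marker gene Mki67 by 0.53 (SE 0.07). Of 27 genes of the unfolded protein response, 19 fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.27. Edem1, which acts in the disposal of misfolded glycoproteins, was lower by a log2 fold change of -0.93 (SE 0.04), the chaperone gene Canx of -0.69 (SE 0.04), the stress sensor gene Atf6 of -0.49 (SE 0.04) and Hspa5, which encodes the chaperone BiP, of -0.42 (SE 0.04). Both lists passed camera at its preset correlation (adjusted p = 9.19e-20 for each) and neither kept its call, with adjusted p = 0.0626 with an estimated correlation for each. Of 23 genes of the amino acid response, 15 fell and 2 rose (17 and 2 adjusted over the list alone), among them the transcription factor genes Atf3 (-0.62, SE 0.06) and Atf5 (-0.53, SE 0.04) and the asparagine synthetase gene Asns (-0.49, SE 0.06). The median was -0.35 (camera adjusted p = 1.24e-12, adjusted p = 0.310 with an estimated correlation). Of 37 interferon response genes, 17 fell and 2 rose (22 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 7.03e-09, adjusted p = 0.582 with an estimated correlation). Among these were the antiviral genes Rsad2 (-0.71, SE 0.10) and Oasl2 (-0.68, SE 0.07) and the regulator gene Irf7 (-0.23, SE 0.04).

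**Figure D2:**
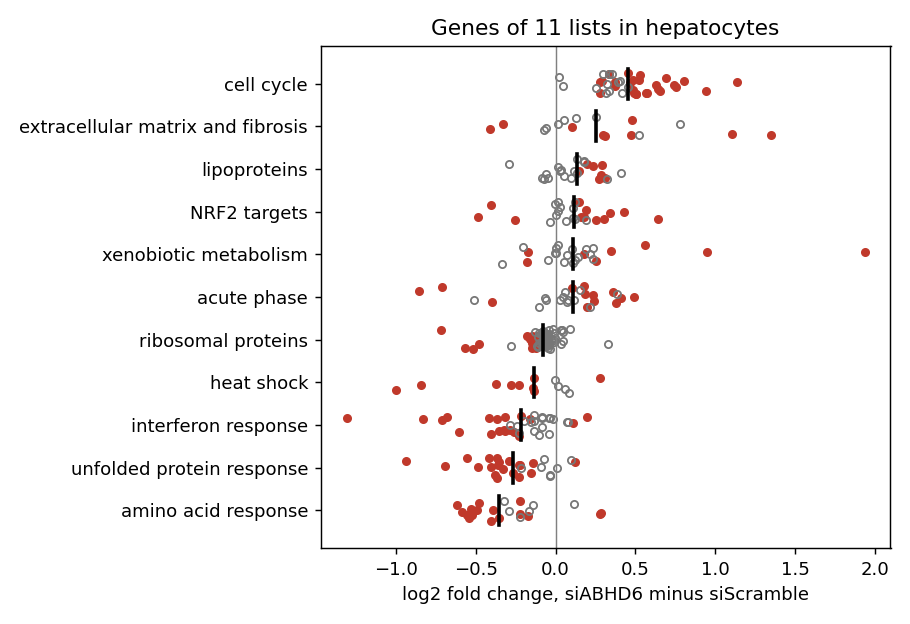
Log2 fold change (siABHD6 minus siScramble) of each gene in the 11 lists that passed camera at the preset correlation in hepatocytes. Filled points passed edgeR's threshold, open points did not, and the vertical bars are list medians, from -0.35 for the amino acid response to 0.45 for the cell cycle.

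Of the other lists that were lower, 17 of 71 ribosomal protein genes fell and none rose (20 and 0 adjusted over the list alone), with a median of only -0.08 (camera adjusted p = 1.22e-05, adjusted p = 0.582 with an estimated correlation). Rpl32 (-0.57, SE 0.04) and Rpl6 (-0.51, SE 0.03) stood well below that median, and both have processed copies in the genome with which reads may be shared. Of 13 heat shock genes, 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.000483, adjusted p = 0.270 with an estimated correlation), including Hspb1 (-0.37, SE 0.04) and Hspa1b (-0.84, SE 0.10), a near copy of Hspa1a. On the higher side, 7 of 24 lipoprotein genes rose and none fell (7 and 0 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00145, adjusted p = 0.486 with an estimated correlation). The lipoprotein receptor gene Lrp1 and the apolipoprotein gene Apoc3 each rose by 0.29 (SE 0.03 and 0.04). Of 17 extracellular matrix genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00263, adjusted p = 0.582 with an estimated correlation). The metalloproteinase inhibitor gene Timp2 (1.35, SE 0.16) and the lysyl oxidase gene Loxl2 (0.47, SE 0.05) rose and the basement membrane collagen gene Col4a1 fell (-0.41, SE 0.05). Stellate cell markers, of which 3 were tested and so too few for camera, included Col1a1, a fibrillar collagen gene that rose (1.11, SE 0.28, edgeR adjusted p = 0.0104, and 0.0565 without siScramble 2 and 0.0628 without siABHD6 3). Their mean log2 CPM, relative to the mean of the 6 cultures, was 0.35, -0.22 and 0.44 in siABHD6 1, 2 and 3, where the matrix list stood at 0.20, -0.02 and 0.25. Col1a1 is on both lists, so these values are not independent of each other. Of 25 xenobiotic metabolism genes, 6 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00868, adjusted p = 0.486 with an estimated correlation), with Aldh1a1, a retinaldehyde dehydrogenase gene, higher by 0.56 (SE 0.04). Of 26 acute phase genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0240, adjusted p = 0.597 with an estimated correlation), among them Hp (haptoglobin, 0.49, SE 0.03), Fgb (fibrinogen, 0.41, SE 0.04) and Steap4 (-0.86, SE 0.06). Of 24 NRF2 targets, 9 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0280, adjusted p = 0.818 with an estimated correlation), among them Gclc, of glutathione synthesis (0.64, SE 0.04), and Ephx1 (-0.49, SE 0.03). Gsta1, Gsta2, Gstm1, Gstm2 and Gstm3 are on both the xenobiotic metabolism and NRF2 lists, so these are not separate results. The camera calls of 3 lists ended without single libraries: xenobiotic metabolism without siABHD6 1 (adjusted p = 0.0662), acute phase without siABHD6 2 or 3 (up to 0.284) and NRF2 targets without siScramble 1, siScramble 2 or siABHD6 1 (up to 0.459).

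Some genes of insulin action passed in hepatocytes, in both directions. Irs1, which encodes an insulin receptor substrate, rose by 0.55 (SE 0.14, edgeR adjusted p = 0.0102), the fatty acid synthase gene Fasn rose by 0.16 (SE 0.04, edgeR adjusted p = 0.0150), and Igfbp1, a FoxO1-responsive gene, was lower (-0.37, SE 0.06, edgeR adjusted p = 9.74e-05). Foxo1 (0.02, SE 0.06), Akt1 (0.09, SE 0.04), Akt2 (0.03, SE 0.04), Insr (-0.03, SE 0.04), Srebf1 (0.07, SE 0.05), Irs2 (0.25, SE 0.09), Ppargc1a (0.31, SE 0.16) and Mgll (0.17, SE 0.08) did not pass. G6pc and Pck1 were too low in these cultures to be tested. In the gluconeogenesis list 4 of 16 genes rose and 2 fell (4 and 2 adjusted over the list alone), with Pcx, the pyruvate carboxylase gene, higher (0.28, SE 0.04) and Pck2 lower (-0.44, SE 0.06). The list did not pass camera (adjusted p = 0.574). In the list of FoxO1-responsive genes 3 of 20 rose and 2 fell (6 and 3 adjusted over the list alone), with Cited2 higher (0.43, SE 0.04). In the list of insulin and Akt signalling 4 of 30 rose and 3 fell (5 and 3 adjusted over the list alone). These lists did not pass camera either (adjusted p = 0.275 and 0.893). Camera tests for a common direction, and fry's test for changes in either direction gave adjusted p = 0.000270, 0.000925 and 0.000453 for gluconeogenesis, FoxO1-responsive genes and insulin and Akt signalling, a test that 34 of the 35 lists passed. Hepatocyte identity genes did not pass as a list (median 0.08, camera adjusted p = 0.107).

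A single edgeR fit over all 12 libraries, in which livers share the estimate of the spread, called 41 genes in hepatocytes, all of them among the 2075, and kept 7 of the 47 genes named above as called besides Abhd6; fry called 5 of the 11 lists (cell cycle, the unfolded protein response, the amino acid response, heat shock and lipoproteins). The edgeR call of Fasn was lost without siScramble 1, siScramble 2 or siABHD6 3 (adjusted p = 0.0999, 0.0555 and 0.0563) and that of Irs1 without siScramble 2 (adjusted p = 0.0627).

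The second comparison asked what changed in livers of mice on the high fat diet when ABHD6 was overexpressed. No gene passed edgeR's threshold among 13910 tested. The iron hormone gene Hamp (hepcidin) was at 519 ± 15.3 CPM (SD, n = 3) with overexpression and at 190 ± 24.9 CPM (SD, n = 3) with GFP, a log2 fold change of 1.45 (SE 0.16), and had the smallest adjusted p in edgeR (0.452). The count at an unadjusted p under 0.05 was 301, where 695.5 are expected by chance, and the groups did not overlap for 6.75% of genes, where chance gives 10%. DESeq2 called 10 genes, named here after their values were seen, of which 4 were higher (Hamp, Abhd6, Resf1 and Cyp4a12b) and 6 lower (among them Igha, Igkc, Hmgcs1, Mvd and Niban2), and limma-voom called 0. The biological coefficient of variation was 28.1% in livers and 4.93% in hepatocytes.

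The genes named by rule in livers did not pass in edgeR's fit of the 6 livers. On the higher side these were Hamp, Resf1 (0.81, SE 0.12) and the ubiquitin ligase gene Rnf5 (0.55, SE 0.11). In other edgeR settings Hamp passed with no filter, in the fit over all 12 libraries and with a covariate for the acute phase list (adjusted p = 0.0441, 0.0452 and 0.0243). Hamp is itself on that list, so this covariate contains it. Resf1 passed in the fit over all 12 libraries (adjusted p = 0.0113). Without single libraries the adjusted p in edgeR was 0.180 to 1.00 for Hamp and 0.557 to 1.00 for Resf1. On the lower side the genes included Niban2 (-1.19, SE 0.22) and the biotin ligase gene Hlcs (-0.71, SE 0.16). The gluconeogenic genes G6pc (1.04, SE 0.30, unadjusted p = 0.0104 in edgeR) and Pck1 (1.04, SE 0.32, unadjusted p = 0.0129) had positive fold changes, Fasn a negative one (-0.97, SE 0.29, unadjusted p = 0.0113), and for each of these 3 genes the groups did not overlap. Their adjusted p-values in edgeR were 1.00. Irs2 (0.39, SE 0.16) and Igfbp1 (0.86, SE 0.52, and 0.12 without overexpressing liver 2) did not pass either, and neither did Irs1 (0.27, SE 0.25), Foxo1 (0.14, SE 0.17), Mgll (0.14, SE 0.27), Insr (0.05, SE 0.17), Srebf1 (0.02, SE 0.17), Ppargc1a (0.02, SE 0.35), Akt2 (-0.08, SE 0.16) and Akt1 (-0.14, SE 0.29).

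In the livers, the gene lists of sterol and fatty acid synthesis were called lower with overexpression, at the preset correlation alone. All 24 cholesterol synthesis genes had negative fold changes, with a median of -1.004, and none passed over all genes tested (3 lower and 0 higher adjusted over the list alone). Hmgcs1, the HMG-CoA synthase gene (-1.60, SE 0.39), Fdps (-1.62, SE 0.42) and Mvd (-1.63, SE 0.42) were among them. In the list of de novo lipogenesis 17 of 20 genes had negative fold changes, with a median of -0.60 and Acly, the ATP citrate lyase gene, at -0.89 (SE 0.32), and none passed by either adjustment, including the one adjusted over the list alone. Camera called both lists lower (adjusted p = 1.68e-33 and 6.94e-08) and neither with an estimated correlation (adjusted p = 0.896 with an estimated correlation for each). The mean log2 CPM of the cholesterol synthesis list, relative to the mean of the 6 livers, was -0.15, -0.94 and -0.30 in overexpressing livers 1, 2 and 3 and -0.26, 0.75 and 0.90 in GFP livers 1, 2 and 3. The groups overlapped (exact two-sided permutation p = 0.2, where 0.1 is the smallest 3 against 3 can give). For the de novo lipogenesis list the groups overlapped too (exact two-sided permutation p = 0.4). It lost its camera call without overexpressing liver 1 (adjusted p = 0.0587).

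Of the other lists, camera called 7 higher at the preset correlation, and none of their genes passed in edgeR. These were fatty acid oxidation and PPARalpha targets (34 of 36 positive, median 0.17), gluconeogenesis (13 of 18 positive, median 0.11), FoxO1-responsive genes (17 of 22 positive, median 0.15), the periportal zone (16 of 18 positive, median 0.22), heat shock (10 of 12 positive, median 0.17), male-biased liver genes (13 of 20 positive, median 0.17) and Kupffer cells and macrophages (17 of 18 positive, median 0.19). Within them Hsph1, a heat shock gene, was at 0.58 (SE 0.17), the male-biased gene Cyp4a12b at 1.89 (SE 0.51) and Angptl8, against the direction of its FoxO1-responsive list, at -0.95 (SE 0.29). Lower were B and plasma cells (3 of 6 negative, median -0.21), red blood cells (5 of 6 negative, median -0.49) and culture dedifferentiation (17 of 22 negative, median -0.15). In the B and plasma cell list the immunoglobulin genes Igkc (-1.28, SE 0.24) and Jchain (-1.51, SE 0.42) were negative and the B cell receptor gene Cd79b (0.32, SE 0.61) was positive, though at -0.39 without overexpressing liver 2. In the B and plasma cell list 2 genes were lower and 0 higher adjusted over the list alone, and in the other 9 of these lists the count was 0. For these 10 lists the camera adjusted p was 0.0489 or lower at the preset correlation, and between 0.896 and 0.948 with an estimated correlation. The exact two-sided permutation p was 0.1, the smallest possible, for heat shock and the periportal zone, and 0.2 to 0.9 for the others. Pck1 is on the gluconeogenesis, FoxO1-responsive and periportal lists, and G6pc and Ppargc1a are on the gluconeogenesis and FoxO1-responsive lists, so these are not separate results. Calls ended without single libraries for B and plasma cells (overexpressing liver 1), the periportal zone (overexpressing liver 2), gluconeogenesis and fatty acid oxidation (GFP 3 or overexpressing liver 3), FoxO1-responsive genes (GFP 3 or overexpressing livers 2 or 3), red blood cells (GFP 3 or overexpressing livers 1 or 3), culture dedifferentiation and male-biased genes (GFP 1, GFP 2 or overexpressing livers 1 or 3) and Kupffer cells (GFP 1, GFP 3 or overexpressing livers 1 or 2), where the highest adjusted p were 0.0638, 0.168, 0.185, 0.185, 0.650, 0.522, 0.702, 0.942 and 0.552. The direction of 3 lists turned, of male-biased genes without GFP 2, of fatty acid oxidation without GFP 3 and of Kupffer cells without overexpressing liver 2 (adjusted p = 0.791, 0.185 and 0.552 there). The heat shock list kept its call without any single library.

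Livers GFP 3 and ABHD6 OE 1 stood apart from the other 4. On the acute phase list their mean log2 CPM, relative to the mean of the 6 livers, was 2.00 and 1.08, and that of GFP 1, GFP 2, ABHD6 OE 2 and ABHD6 OE 3 was -0.75, -0.89, -0.61 and -0.83. The fatty acid oxidation list stood at -1.49 in GFP 3 and -0.42 in ABHD6 OE 1, and between 0.32 and 0.55 in the other 4. The de novo lipogenesis list stood at -0.31 and -1.06 in these livers and at 0.51, 0.65, -0.01 and 0.22 in GFP 1, GFP 2, ABHD6 OE 2 and ABHD6 OE 3. Female-biased genes stood at -2.80 and -1.32 in GFP 3 and ABHD6 OE 1 and at 1.28, 1.32, 1.16 and 0.36 in the others in that order, and male-biased genes, a list called above, at 1.73 and 1.66 and at -0.64, -2.06, -1.36 and 0.67. Without these 2 livers, edgeR called 1 gene (the immunoglobulin gene Igha, named after its values were seen, log2 fold change -3.33), and camera called 19 lists at the preset correlation, which included 10 of the 12.

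**Figure D3:**
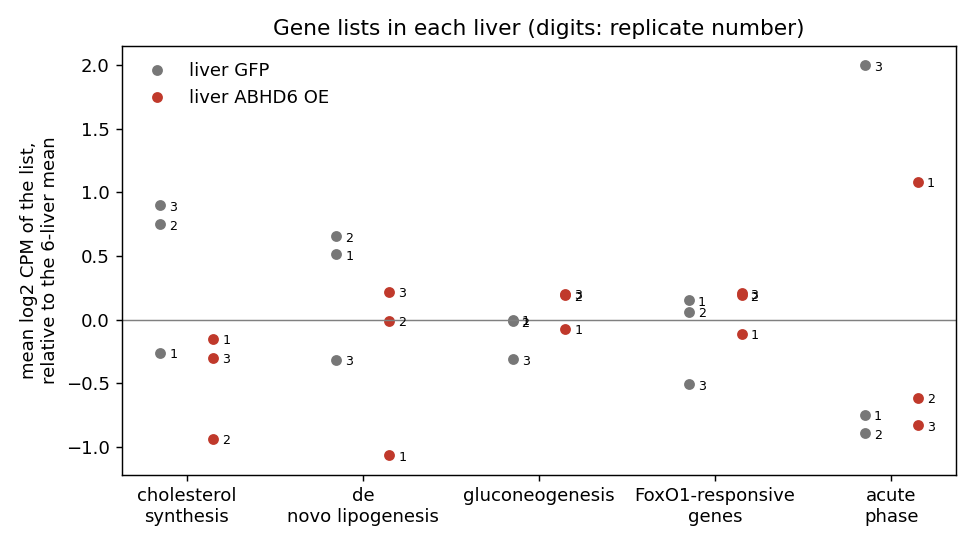
Mean log2 CPM of 5 gene lists in each liver, relative to the mean of the 6 livers, with replicate numbers beside the points. GFP 3 (2.00) and ABHD6 OE 1 (1.08) are high on the acute phase list, and the groups overlap on each list shown.

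The third comparison asked whether the response to overexpression in livers differed from the response to knockdown in hepatocytes, so that system and manipulation go together in it. Among 15244 genes in a single edgeR fit, 19 differed, of which 15 had the higher log2 fold change in livers and 4 the lower. No gene passed in edgeR's fit of the 6 livers, so a difference need not mean a response in livers. The difference (liver minus hepatocyte response, log2) was 4.79 (SE 0.33) for Abhd6 and 2.19 (SE 0.14) for Iscu, with an adjusted p of 6.72e-05 for both. For Iscu this was close in size to its log2 fold change of -2.24 in hepatocytes. Other genes, named after their values were seen, were Csf1, a macrophage growth factor gene (-1.03, SE 0.10), the mitochondrial complex I gene Ndufa2 (0.87, SE 0.10), Cth, of cysteine synthesis (0.89, SE 0.13), and the uncoupling protein gene Ucp2 (-1.25, SE 0.20), with edgeR adjusted p-values of 0.0491 or lower. All but Resf1 were also among the genes called in hepatocytes. The count was 58 without GFP 3, 9 without ABHD6 OE 3, 7, 7 and 8 without siScramble 1, 2 and 3, 8, 5 and 4 without siABHD6 1, 2 and 3, 166 without livers GFP 3 and ABHD6 OE 1, and 2 with the replicate number as a block. DESeq2 called 96 genes, which included the 19.

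Fold changes in the systems showed no correlation across genes, which says little about a shared response given the spread between livers (a coefficient of variation of 28.1%). Over the 12243 genes other than Abhd6 tested in both, Pearson's r was 0.009 and Spearman's rho 0.0003 across genes, which are not independent replicates, and 49.5% had opposite signs. Among the 1972 of them called in hepatocytes, r was 0.013, rho was -0.048 and 51.5% had opposite signs. No gene was called by edgeR in both comparisons, since none was called in livers, where 301 had an unadjusted p under 0.05. DESeq2 called 1 gene in opposite directions in both, which was Abhd6 itself. Of genes tested in both with an unadjusted p under 0.05 in livers, a threshold chosen after no liver gene passed, 11 higher in livers were called lower in hepatocytes where independent lists give 8.25, and 17 lower in livers were called higher where they give 12.3. In the same direction, 16 were lower in both where independent lists give 12.2, and 7 higher in both where they give 8.34. The one-sided Fisher's exact test gave adjusted p = 0.268 for the first 3 pairs and 0.739 for the last.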

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

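Leaving out livers GFP 3 and ABHD6 OE 1, and the acute-phase covariate, were chosen after the data were seen, and the other settings before. No Abhd6 value below changed direction, while the balance of higher and lower calls in hepatocytes turned with upper-quartile scaling. The cause of each change was not tested except where the setting's construction shows it. Single lists in livers turned direction, and lost their call: male-biased genes without GFP 2, fatty acid oxidation without GFP 3, Kupffer cells without ABHD6 OE 2 and red blood cells without both GFP 3 and ABHD6 OE 1 (adjusted p = 0.791, 0.185, 0.552 and 0.973). Genes called in livers numbered 0 in edgeR (301 at an unadjusted p under 0.05) and 0 without any single library, with RLE or upper-quartile scaling, limma-voom, the strict filter, FPKM or protein-coding genes only. They numbered 2 with no filter, 10 with DESeq2, 4 in a single fit over all 12 libraries, 1 without the 2 livers and 3 with the covariate. Genes called in hepatocytes (2075) numbered 1468 (without siScramble 2) to 1873 (without siABHD6 2) when single libraries were left out, 1313 with FPKM (1238 of them shared), 41 in a single fit over all 12 libraries and 274 with a fold of at least 1.5, which can only remove genes. The share of called genes that were higher was 50.7%, and 49.2% to 51.0% under the other scalings and tools. With upper-quartile scaling lower calls outnumbered higher ones (1051 against 1018). Liver Abhd6 (log2 fold change 2.04, not called) was 1.83 to 2.24 without single libraries and was called at 2.04 with DESeq2 and at 2.04 in the fit over all 12 libraries. Hepatocyte Abhd6 kept its call in every setting run, at -2.79 to -2.73 without single libraries. Lists called in livers (12) numbered 0 with an estimated correlation, 0 with fry, 19 without the 2 livers and 9 (without ABHD6 OE 3) to 21 (without GFP 3) without single libraries. Lists called in hepatocytes (11) numbered 0 with an estimated correlation, 8 with fry (5 of them among the 11) and 10 to 12 without single libraries. Genes whose responses differed (19) numbered 96 with DESeq2, 166 without the 2 livers and 4 (without siABHD6 3) to 58 (without GFP 3) without single libraries; the count was also 9 without ABHD6 OE 3, 7, 7 and 8 without siScramble 1, 2 and 3, and 8 and 5 without siABHD6 1 and 2. Genes called in both comparisons in opposite directions (0) numbered 1 with DESeq2, 1 with no filter and 0 without any single library. With the replicate block, counts were 0 in livers, 2124 in hepatocytes, 2 for the response difference, 11 lists in each system and 0 in both comparisons, and Abhd6 was at 2.05 and -2.77. For named genes, 245 of 252 values in livers and 489 of 495 in hepatocytes stayed on their side of the threshold; DESeq2 gained 7 in livers, and edgeR settings outside these values gained Hamp (no filter, the fit over all 12 libraries and the covariate) and Resf1 (the fit over all 12 libraries), and 6 calls were lost in hepatocytes without single libraries (Fasn 3 times, Col1a1 2 times and Irs1 1 time, with adjusted p up to 0.0999, 0.0628 and 0.0627). Of 47 named genes called in hepatocytes besides Abhd6, the fit over all 12 libraries kept 7 (Canx, Dio3, Edem1, Eef1akmt4, Iscu, Pcsk6 and Serpinb9b) and lost 40, the strict filter lost 2 (Eef1akmt4 and Hrk), and FPKM lost 3 with a pseudocount of 1 (Col1a1, Fasn and Mup15) and 4 with 0.1 (also Irs1). Depth was similar in both systems, while edgeR's coefficient of variation was 28.1% in livers and 4.93% in hepatocytes.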

Other observations

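Tests of a label swap, of neutrophil RNA, and of all explanations for the sterol genes were chosen after their results were seen; the test of Abhd6 transcripts was written after the words were known but before the transcripts were searched. Livers GFP 3 and ABHD6 OE 1 had acute phase transcripts far above the other 4; the genes named for them were chosen after their values were seen. Saa1, which encodes serum amyloid A, was at 6105 CPM in GFP 3 and 1839 CPM in ABHD6 OE 1, and at 60.8, 32.7, 87.1 and 31.6 CPM in GFP 1, GFP 2, ABHD6 OE 2 and ABHD6 OE 3. Lcn2 (lipocalin 2) was at 1091 and 210.5 CPM, against 16.4, 8.82, 20.1 and 4.63 CPM in the same order. Scd1, of fatty acid desaturation, was at 2705 and 1006 CPM, against 22299, 22227, 18470 and 11856 CPM. The PPARalpha target Cyp4a14 was at 3.15 and 150 CPM, against 700, 840, 726 and 564 CPM, whereas the cholesterol synthesis list was higher in GFP 3 than in any other liver (0.90 relative to the mean). Albumin took 4.88% and 3.83% of their counts, against 7.54% to 8.68%. The first principal component of the livers (54.2% of variance) placed them at 64.4 and 34.7 and the others between -36.0 and -5.01.

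Livers and cultures were not tested against each other, since system, diet and treatment differ together. Hepatocyte identity genes summed to 105972 ± 22350 CPM and 108152 ± 12476 CPM in overexpressing and GFP livers, and to 19801 ± 281 CPM and 19953 ± 149 CPM in siABHD6 and siScramble hepatocytes (SD, n = 3 each).

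Off-target pairing of the ABHD6 siRNA through its seed, a 7-base stretch that can lower other transcripts, is a candidate explanation for part of the decreases in hepatocytes, although the siRNA sequence was not given in the sources used here. Of 16095 words scanned, 3 passed the limit of 4.67 on the positive side: GAATATA, the highest, TGAATAT and AGAATAT (t of 7.68, 6.85 and 5.77). Increases thus went with words in 3' UTRs too, and the cause of this was not tested. The controls received an siRNA too, the scrambled one, so pairing of either siRNA stays open for genes in both directions. The lowest t was that of CTACGCA (-8.29). It was held by 4.39% of fallen and 0.687% of risen genes, the same genes it was picked from, and had a t of 0.598 in livers. The Abhd6 3' UTR lacks this word, which was seen before the transcripts were searched, and it or GCTACGC, which overlaps it by all but 1 base, occurred in 3 of 3 coding Abhd6 transcripts, which share sequence, where 9.54% of genes' longest transcripts hold one. In livers 1 word passed the negative limit (CCCATCC, t of -4.74), and in hepatocytes 9 did. Of 979 fallen genes, 558 held none of these 9 words, among them Eef1akmt4 and Hspa5. At least 1 was held by 43.0% of fallen, 27.2% of risen and 29.2% of all genes searched. Holders among fallen genes included Pcsk6, Steap4, Iscu, Edem1, Canx and Atf6, and among risen genes Serpinb9b, Irs1, Cited2 and Aldh1a1. None of this is further evidence, since the 9 words were picked on the same fold changes. Of the unfolded protein response genes that fell, 36.8% held at least 1 (7 of 19, 95% binomial interval 16.3% to 61.6%), against 29.2% of all genes, and seed pairing and loss of ABHD6 cannot be told apart for this list: its value met the criterion written against pairing, but not by more than its interval, a condition added after the value was seen, and loss of ABHD6 stays open for the other genes too.

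For the acute phase signal in livers GFP 3 and ABHD6 OE 1, a swap of these labels was argued against by Abhd6, which was higher in ABHD6 OE 1 than in GFP 3 by 2.90 on the log2 scale. Neutrophil RNA was argued against by S100a8 plus S100a9, which came to at most 0.00474 times Lcn2 in either liver. No biological explanation was tested, since the labels give none for these 2 samples. Their mean log2 CPM on the lipid droplet and steatosis list was also low, at -1.14 in GFP 3 and -0.63 in ABHD6 OE 1. It was 0.83, 0.31, 0.54 and 0.09 in GFP 1, GFP 2, ABHD6 OE 2 and ABHD6 OE 3, each relative to the mean of the livers. Illness of the animals, tissue handling, a weaker response to the diet and a difference in sex were not tested and stay open.

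For the lower sterol synthesis genes in overexpressing livers, the list median was -0.89 without the 2 acute phase livers (24 of 24 genes negative). This left 2 livers per group, with list means of -0.26 and 0.75 in GFP 1 and 2 and -0.94 and -0.30 in ABHD6 OE 2 and 3. Genes of the list moved together (estimated correlation 0.668), so the 24 are not separate results. The direction thus stayed without the acute phase livers, but so few livers cannot decide their part in it. A lower share of hepatocyte RNA was argued against by a median of -0.00353 for hepatocyte identity genes. Of the 10 splits of the 6 livers, 3 gave a median as far from 0 (1.004 for the real split, 1.12 at most for another), and the splits are too few for a share under 0.05. An effect of ABHD6 overexpression may be among the causes, as a hypothesis, beside differences between single animals, which stay open with 3 livers per group.

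Other splits of the same libraries were counted for each result across genes. With 3 against 3 the 10 splits are too few for a share under 0.05: genes called in livers were 0 for the real split and 2 at most for another (10 of 10 splits gave as many), lists called in livers 12 and 26 (8 of 10), genes called in hepatocytes 2075 and 2 (1 of 10) and lists called in hepatocytes 11 and 10 (1 of 10). For the difference between responses, 13 of 100 splits called at least 19 genes, with 50 at most, so chance cannot be excluded. Besides the real split, 6 of the 100 kept the hepatocytes as labelled and with them the knockdown (44 genes at most). The split with 50 calls mixed the hepatocyte groups, and structure among the libraries other than the groups may be behind it, which was not tested.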
